A study of Rattus norvegicus with 32 samples.

How the data were processed

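RNA from 16 cultures of rat epithelial cells was measured on Affymetrix rat gene arrays, with 2 arrays per culture and 32 arrays in all. Per the labels, total RNA was amplified and biotin-labelled with the whole transcript sense target protocol. The values are log2 probe set signals that the authors made by RMA in Affymetrix Expression Console, per the submitters' processing notes. The notes name no software version, background setting or annotation release. The log base was read from the values, which ran from 1.526 to 14.03 and which RMA writes on the log2 scale. No value was transformed again, and no array was pooled with another before deposition.

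The deposited table held 29215 probe sets. Of these, 15316 carried exactly 1 gene symbol, 317 carried several and 13582 had no listed gene. The 15316 probe sets, which stand for 14511 genes, were tested, and 528 genes had more than 1 probe set. The Entrez gene of 15279 of them was found in the RefSeq gene table of the rat genome, and 0 symbols needed updating. Probe sets were counted, not merged, and no filter on level was applied. The number of cultures, not of arrays, limits the precision of the tests, and an array has no count depth.

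Cultures were grouped by tissue of origin and by the number of transplantations, as the labels give them. The groups were thymic epithelial cell (TEC) cultures before grafting (4 cultures), after a first transplantation (4) and after a second (4), and hair follicle (HF) cultures before grafting (2) and after a first transplantation (2). The arrays of a culture share its name, so the culture was the unit: both arrays of each culture were averaged first. The groups, the comparisons, the gene lists, the rule for named genes and all alternatives except those described below as added were fixed before the data were examined.

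Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the 16 culture means with 1 coefficient per group. All 5 groups shared 1 estimate of the spread, because the HF groups hold 2 cultures each. P-values were adjusted with the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was taken as past the threshold. The comparisons were TEC with HF before grafting, each grafted TEC group with TEC before grafting, both grafted TEC groups with each other, HF after with HF before grafting, and each grafted TEC group with grafted HF. The interaction of tissue and first transplantation was tested as a difference of differences. Donor age (4 months against embryonic day E16) was tested within the 12 TEC cultures with the transplantation state in the model. The errors given with log2 differences are limma standard errors (SE), and those given with group levels are standard deviations (SD) between cultures. The 95% intervals were computed but are not printed.

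For each TEC culture the root mean square log2 difference from the mean of the HF cultures was computed over the 15316 probe sets. These distances were compared between TEC states with two-sided exact permutation tests. The share of the starting TEC to HF difference covered after grafting was the slope across genes, with one part of the ungrafted TEC cultures used to choose the genes and the other part used to measure the change. All 6 such divisions of the 4 cultures were run.

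Of 29 gene lists fixed beforehand, 28 had at least 3 measured members and were tested with camera in limma, with a preset correlation between genes of 0.01 and again with an estimated correlation. The lists were thymic epithelial identity regulators, thymic epithelial function, MHC class II and class I presentation, interferon response, hair follicle stem cell and placode, hair shaft and inner root sheath, basal keratinocyte and hemidesmosome, epidermal differentiation, surface ectoderm transcription factors, simple and endodermal epithelium, sebaceous and lipid synthesis, Hox paralogues of low and of high number, the Wnt, BMP and TGF-beta, Notch and Hedgehog pathways, cell cycle, p53 and senescence, inflammatory and wound response, and markers of fibroblasts and feeder cells, melanocytes, haematopoietic cells, endothelium, nerve, parathyroid and thyroid, and muscle. The list of sex-linked transcripts had 1 measured member and was not tested. Members past the threshold were counted among all genes and with p-values adjusted over the list alone.

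The text names genes by a fixed rule: the 10 largest increases and 10 largest decreases past the threshold whose culture values did not overlap between the groups in each main comparison (5 and 5 in the others), up to 4 members of each list past the threshold, a fixed panel, and, where nothing passed, the genes with the smallest p. Some of these genes are not printed. Background levels were not analysed here, so a signal under 4, a limit chosen after the values were seen, was not taken as shown to lie above background. Genes that passed only when adjusted over their list alone are outside this rule, and where they are named they were chosen after their values were seen. Of the panel, Hoxa3, Eya1, Tbx1, Krt5 and Sox9 were not measured by a probe set of that name, and Trp63 was measured as Tp63.

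The calculation was tested on simulated data with 15316 genes of which 200 were changed, in 5 simulations. Between TEC groups it recovered 86.8% to 88.2% of changes of 2-fold, and in comparisons with HF cultures 71.4% to 78.8%. The interaction recovered 53.6% of them and the donor age comparison 85.4%. The mean number of false calls was 8.2 to 10.2, and 0 calls had the wrong direction. Camera called a list of 20 genes shifted by 0.5 in 20 of 20 simulations, and 3 of 540 other lists. The simulated genes varied independently and the lists were drawn at random. These rates therefore do not show how often false calls arise among correlated genes or cultures.

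The alternatives fixed beforehand were another quantile normalization of the arrays, centring each array on its median, a filter on probe sets below the median level, all probe sets of the table, eBayes with trend and robust settings, donor stage of the TEC cultures as a covariate, only the cultures compared in the fit, clonal cultures only, all 32 arrays with culture as a random block, the same with the array number as a replicate block, and leaving out each culture in turn. The random block fits assumed 1 correlation between the arrays of a culture for all genes. Their p-values are therefore too small for genes that vary more between cultures than this correlation implies. After the data were seen, fits without array 1 of YR219P5_RC and without array 2 of Clone_347 were added. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.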

Results

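Gene expression was measured in cultured epithelial cells of rats that express green fluorescent protein. Thymic epithelial cells (TEC), which line the thymus and guide the development of T cells, and hair follicle (HF) cells were grown as clones or bulk cultures on irradiated 3T3-J2 mouse fibroblasts. Some were transplanted into skin on nude mice, recovered and grown again. The series compares TEC with HF cells before and after transplantation, and the underlying question was whether thymic cells exposed to skin acquire features of hair follicle cells. The 12 TEC cultures comprised 4 before grafting, 4 after a first and 4 after a second transplantation. They came from embryonic day 16 (5 cultures), postnatal day 1 (3) and 4-month-old (4) donors. The 4 HF cultures, all labelled P5 without further explanation, comprised 2 before and 2 after a first transplantation. No TEC culture carries that label, so TEC and HF cultures could not be compared apart from donor stage. In total 11 cultures were clonal and 5 were bulk. Array medians lay between 5.287 and 5.554, except array 1 of the grafted HF bulk culture YR219P5_RC at 5.782. The arrays of a culture correlated at 0.9889 (Clone_347) to 0.9979 (Clone_57) across probe sets, and different cultures at 0.9552 to 0.9957. Probe sets are not independent replicates. No comparison could be adjusted for an array batch, since the labels give none.

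Before grafting, Krt8, a keratin of simple epithelia (probe set 10751352), was 20.8-fold higher in TEC cultures (11.27 ± 0.33, SD, n = 4) than in HF cultures (6.89 ± 0.32, n = 2; log2 difference 4.38 ± 0.66 SE, adjusted p = 0.007). The transcription factors Isl1 and Pax9, both active in the pharyngeal endoderm from which the thymus forms, were 6.87-fold and 6.61-fold higher in TEC cultures (adjusted p = 0.000843 and 0.0131). The other Krt8 probe set differed by 5.78 (adjusted p = 0.0045). Lgals7, the galectin of stratified epithelia (probe set 10705654), was 62.1-fold lower in TEC cultures (5.10 ± 0.23 against 11.05 ± 0.32). Hoxa5, which gives positional identity along the body axis, was 2.63-fold higher.

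The comparison of TEC with HF cultures before grafting asked how far the starting points lie apart. Other genes higher in TEC cultures were Serpinb7, a protease inhibitor (69.9-fold), Slc38a4, an amino acid transporter (26.3-fold), Ptgs1, which encodes cyclooxygenase 1 (24.4-fold), Mme, which encodes neprilysin (16.3-fold), Rgs2 (13.7-fold), Cdc42ep5 (log2 3.70), Steap1 (10.6-fold) and Sp100 (10.4-fold). Genes lower in TEC cultures included Bhlhe41, a transcriptional repressor (18.8-fold), Lrat, which esterifies retinol (15.3-fold), Prss23 (14.1-fold), Nedd9 (8.80-fold), Rassf4 (6.88-fold), Atp2b4 (6.06-fold), Vamp5 (5.84-fold), Ctnnal1 (4.89-fold) and Nfasc (4.65-fold). For all of these the culture values of the groups did not overlap. The lower levels of Mme (3.54), Lrat (3.84) and Bhlhe41 (3.85), and of Serpinb7 (3.75) and Sp100 (3.75) in YR219P5_Bulk_V, were not shown to lie above background, so these folds are lower bounds. Without YR219P5_Bulk_V and without YR219P5cl7 the log2 differences were 5.22 and 7.04 for Serpinb7, 5.24 and 2.31 for Rgs2, 2.61 and 4.14 for Sp100, −1.66 and −3.54 for Atp2b4 and −1.57 and −2.87 for Nfasc. Of 15316 probe sets, limma called 238, 148 higher and 90 lower in TEC cultures. With each array centred on its median the split was 171 and 61.

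The thymic epithelial identity list was higher in TEC cultures before grafting (camera adjusted p = 0.0172; median log2 difference 0.54), but adjusted p = 0.212 with an estimated correlation. Of its 8 measured members, Pax9 (log2 2.73 ± 0.47 SE) and Isl1 (2.78 ± 0.29) were higher, Gata3, a factor of thymus and skin, was lower (−2.06 ± 0.45), and 5 did not pass. Adjusted over the list alone 3 were higher, Pax1 among them, and 1 was lower. Foxn1, the regulator of thymic epithelial maturation, differed by 0.26 ± 0.20 (adjusted p = 0.66). The hair follicle stem cell and placode list was lower in TEC cultures (median −0.45; camera adjusted p = 0.00567), also with adjusted p = 0.212 with an estimated correlation. None of its 19 measured members passed over all genes (0 of 19). Adjusted over the list alone Lhx2, Lgr5, Shh, Msx2 and Vdr were lower. Lhx2, a regulator of hair follicle stem cells, differed by −1.72 ± 0.49 (adjusted p = 0.109, and 0.00228 with culture as a random block, whose p can be too small). Without YR219P5_Bulk_V neither list passed (adjusted p = 0.0663 for each).

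Members of 8 other lists passed in the same comparison although the lists did not. In the Wnt list Wnt4 (2.56-fold) and Wnt7b (3.53-fold; log2 2.65 without YR219P5_Bulk_V and 0.99 without YR219P5cl7), both secreted ligands, were higher in TEC cultures and the receptor Fzd2 was lower (1.54-fold), with 25 of 28 not past. Wnt4 also stands in the thymic epithelial function list, where 16 of 17 members did not pass. Plaur, the urokinase receptor (3.53-fold), and Lcn2, a secreted lipocalin (1.85-fold), were higher in the inflammatory list. Single members were higher in the interferon list (Isg15, 2.61-fold), the BMP and TGF-beta list (Bmpr1b, 3.59-fold), the sebaceous and lipid list (Dgat2, 3.03-fold), the simple epithelium list (Krt8) and the Hox list (Hoxa5). Krt14, a basal keratin, and Tp63, a regulator of stratified epithelia, differed by 0.10 ± 0.10 and −0.60 ± 0.22 (adjusted p = 0.753 and 0.219). With culture as a random block, whose p can be too small, Tp63 passed (adjusted p = 0.0209).

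The number of genes called between TEC and HF cultures before grafting depended on single cultures. It was 18 without YR219P5_Bulk_V, 375 without YR219P5cl7, 113 without PRP4mo_Cl09, 122 without PRP4mo_bulk, 138 without PRE16cl11_VII, 154 without PRP1cl11_VII and 4 with clonal cultures alone. Of the 32 different genes that the fixed rule selected, Cdc42ep5, Isl1, Ptgs1, Steap1 and Slc38a4 stayed past the threshold whichever culture was left out. The calls of the other 27 ended in at least 1 case, with adjusted p of 0.051 to 0.36. The number ended was 25 without YR219P5_Bulk_V (Krt8, Pax9, Lgals7 and Hoxa5 among them), 14 without YR219P5cl7 (Lgals7 among them), 12 without PRP4mo_Cl09, 11 without PRP4mo_bulk, 10 without PRE16cl11_VII and 9 without PRP1cl11_VII. It was 7 without YR219P5_RC or Clone_54, 5 without Clone_907, 4 without Clone_354, 3 without Clone_217 or Clone_194 and 1 without Clone_218 or Clone_57. With the arrays as the unit and culture as a random block, 977 genes were called, and with the donor stages of the TEC cultures in the model 423, which leaves the difference in stage between the tissues in place. The receptor Fzd2 did not pass with the arrays centred on their medians (adjusted p = 0.0524).

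After a first transplantation, TEC cultures rose in Lgals7, the squamous galectin, by 35.4-fold (5.10 ± 0.23 to 10.24 ± 2.21, SD, n = 4 each; adjusted p = 0.0244). The level in Clone_218 was 6.94, and in the other 3 cultures 11.18 to 11.44 (log2 change 6.25 without Clone_218). Enpp1, an enzyme that makes pyrophosphate, rose 5.74-fold (7.02 ± 0.37 to 9.54 ± 0.62; adjusted p = 0.00312). Cdc42ep5, an effector of the GTPase Cdc42, fell 10.9-fold (10.65 ± 0.39 to 7.20 ± 0.85; adjusted p = 0.00312), and its level in HF cultures before grafting was 6.95 ± 0.21. Has2, which makes hyaluronan, fell 14.7-fold, and Plaur fell 3.72-fold (adjusted p = 0.03 and 0.0244).

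**Figure D1:**
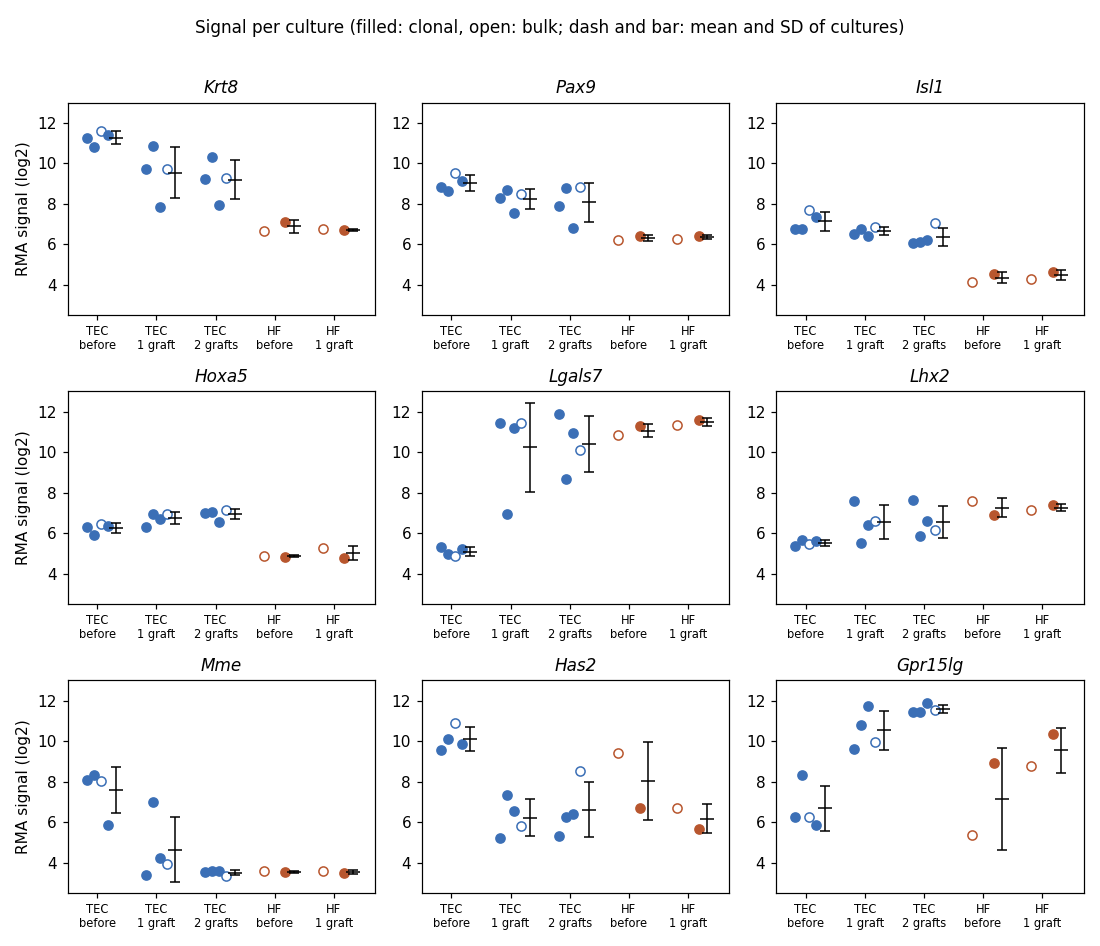
Log2 signal of 9 genes (vertical axes) in the 16 cultures, grouped by tissue and number of transplantations (horizontal axes); points are cultures (mean of 2 arrays; filled for clonal, open for bulk), and bars give the group mean and SD. Lgals7 stood at 5.10 in TEC cultures before grafting and at 10.24 and 10.41 after a first and second transplantation, while Hoxa5 stood at 6.25, 6.74 and 6.94 in these groups and at 4.86 and 5.01 in HF cultures.

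The first transplantation comparison asked what changes in TEC cultures after exposure to skin. The grafted cultures carry other names than the ungrafted ones, and the labels give no ungrafted culture that was recovered and grown again. Exposure to skin therefore cannot be told apart from selection of cells, recovery or further culture. Other genes that rose were Gpr15lg, a secreted ligand (14.4-fold), Ocm, a calcium-binding protein (10.7-fold), Casp1, the inflammasome caspase (7.30-fold), Nupr1, a stress-response factor (6.45-fold), Sh3rf2 (3.48-fold), Scd, the stearoyl-CoA desaturase (3.32-fold), Gadd45g (2.99-fold) and B3gnt3 (2.97-fold). Other genes that fell were Slc38a4 (8.50-fold), F2rl2, a thrombin receptor (5.86-fold), Snurf, an imprinted gene (5.75-fold), Nts, which encodes neurotensin, Fst, the activin antagonist follistatin (4.35-fold), Tram1l1 (4.11-fold) and Grb10, an imprinted adaptor (4.00-fold). The culture values of the groups did not overlap for any of them. The lower levels of Casp1 (3.68), and of Grb10 in Clone_907 (3.97), were not shown to lie above background, so these folds are lower bounds. No fold is given for Nts, since its levels after grafting (3.07) and in ungrafted PRP1cl11_VII (3.78) were not shown to lie above background either. Pax9 differed by −0.80 ± 0.38 (adjusted p = 0.352), Lhx2 by 1.00 ± 0.40 (adjusted p = 0.26), Foxn1 by −0.01 ± 0.16 (adjusted p = 0.983), Krt14 by −0.11 ± 0.08 (adjusted p = 0.593), Tp63 by 0.12 ± 0.18 (adjusted p = 0.824) and Cd74 by −0.85 ± 0.53 (adjusted p = 0.482). With culture as a random block, whose p can be too small, Lhx2 passed (adjusted p = 0.0332).

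After a first transplantation, 3 lists passed with camera. Surface ectoderm transcription factors were higher (median log2 0.26, adjusted p = 0.0336, but adjusted p = 0.831 with an estimated correlation), with 0 of 16 members past over all genes and 0 adjusted over the list alone. Inflammatory and wound response genes were lower (median −0.31, adjusted p = 0.00771, but adjusted p = 0.491 with an estimated correlation): of 25 members Plaur and Lcn2 (1.77-fold) fell and 23 did not pass, and adjusted over the list alone 4 were lower, Ccl2 and Csf2 being the others. Fibroblast and feeder cell markers were lower (median −0.23, adjusted p = 0.00115, but adjusted p = 0.491 with an estimated correlation), with 0 of 22 past over all genes and Twist1 and S100a4 lower when adjusted over the list alone. The surface ectoderm list did not pass without PRE16cl11_VII (adjusted p = 0.106), Clone_217 (0.13), Clone_57 (0.052) or Clone_907 (0.0643), and the inflammatory list did not pass without PRE16cl11_VII (0.106). Single members of other lists passed: Isg15 of the interferon list fell (2.13-fold), Fst of the BMP and TGF-beta list fell and Scd of the sebaceous and lipid list rose. The hair follicle stem cell list had 0 of 19 members past, and Vdr was higher when adjusted over the list alone (camera adjusted p = 0.397).

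Between TEC cultures after a first transplantation and before grafting, limma called 79 probe sets, 33 higher and 46 lower. The count was 8 without Clone_217, 9 without PRP4mo_bulk, 13 without PRP4mo_Cl09 or Clone_907, 49 without PRP1cl11_VII, 136 without YR219P5_Bulk_V or YR219P5cl7 and 148 without Clone_57. With clonal cultures alone limma called 0, with 1308 at an unadjusted p under 0.05. The count was 17 with only the cultures compared in the fit, 143 with donor stage in the model and 1183 with culture as a random block. Of the 22 genes named as changed, Enpp1, Cdc42ep5 and Tram1l1 stayed past the threshold whichever culture was left out. The calls of the other 19 ended in at least 1 case (adjusted p of 0.0502 to 0.181). All 19 ended without Clone_217 and without PRP4mo_bulk, 18 without PRP4mo_Cl09 or Clone_907, 10 without PRP1cl11_VII, 8 without Clone_218, 6 without YR219P5_RC or Clone_54, 5 without PRE16cl11_VII, 2 without Clone_57 and 1 without Clone_287, Clone_347, Clone_194 or Clone_354. Gadd45g and Lcn2 did not pass with the arrays centred on their medians (adjusted p = 0.0595 and 0.0634).

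After a second transplantation, Lgals7 of TEC cultures stood 39.7-fold above the ungrafted level (to 10.41 ± 1.37, SD, n = 4; adjusted p = 0.00882), and Ocm rose 28.7-fold (5.98 ± 0.66 to 10.82 ± 0.29; adjusted p = 0.00113). Mme, which encodes neprilysin, fell at least 16.7-fold to 3.51 ± 0.13, a level not shown to lie above background, beside 3.54 ± 0.04 in ungrafted HF cultures. Krt8 fell 4.26-fold (11.27 ± 0.33 to 9.18 ± 0.97; adjusted p = 0.0482), and its level in HF cultures was 6.89 ± 0.32. The other Krt8 probe set differed by −2.23 and did not pass (adjusted p = 0.068). Gata3 rose 3.53-fold (7.51 ± 0.62 to 9.33 ± 0.47), and its level in HF cultures was 9.57 ± 0.35.

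The second transplantation comparison asked what changes in TEC cultures after repeated exposure to skin. Here too exposure cannot be told apart from selection of cells, recovery or further culture. Other genes that rose were Gpr15lg (29.7-fold), Sult1d1, a sulfotransferase (11.4-fold), Nupr1 (9.49-fold), Acap1 (7.28-fold), Epas1, a hypoxia-inducible factor (5.86-fold), Igfbp2, which binds insulin-like growth factors (5.78-fold), Ceacam1, a cell adhesion molecule (5.77-fold) and Sh3rf2 (5.55-fold). Other genes that fell were Cdc42ep5 (13.2-fold), Upk1b, a uroplakin (12.8-fold), Akap12 (11.8-fold), Has2 (11.2-fold), Slc38a4 (10.3-fold), Chrm3, a muscarinic receptor (8.78-fold), Loxl1, which cross-links elastin (6.92-fold), Snurf (5.94-fold) and Nts. The culture values did not overlap for any of these. The level of Sult1d1 in PRP1cl11_VII (3.64) was not shown to lie above background, so this fold is a lower bound. No fold is given for Nts, whose levels after grafting (2.97) and in PRP1cl11_VII (3.78) were not shown to either. Without Clone_194 the log2 changes of Acap1 and Sult1d1 were 3.60 and 4.15, and without Clone_354 that of Has2 was −4.11. Pax9 differed by −0.98 ± 0.38 and Lhx2 by 1.02 ± 0.40 (adjusted p = 0.168 for each). With culture as a random block both passed (adjusted p = 0.0125 and 0.0191), but that p can be too small for genes that vary strongly between cultures. Foxn1 differed by −0.07 ± 0.16 (adjusted p = 0.886), Krt14 by −0.17 ± 0.08 (adjusted p = 0.264), Cd74 by −0.71 ± 0.53 (adjusted p = 0.51) and Tp63 by 0.44 ± 0.18 (adjusted p = 0.178, and 0.0255 with culture as a random block).

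After a second transplantation 3 lists passed with camera, and each had adjusted p = 0.632 with an estimated correlation. MHC class I presentation was lower (median log2 −0.31, adjusted p = 0.004): of 12 members the immunoproteasome subunits Psmb9 (2.24-fold) and Psmb10 (1.67-fold) and the proteasome activator Psme2 (1.68-fold) fell and 9 did not pass. Adjusted over the list alone 5 were lower, Tap2 and Psme1 being the others. Surface ectoderm transcription factors were higher (median 0.38, adjusted p = 0.00529): Klf4 (1.69-fold) and Prdm1 (1.79-fold, with overlapping culture values), both regulators of epidermal differentiation, rose, 14 of 16 did not pass, and 6 were higher when adjusted over the list alone. Fibroblast and feeder cell markers were lower (median −0.30, adjusted p = 0.00131): Twist1, a mesenchymal transcription factor (2.32-fold), and S100a4 (3.25-fold) fell, 20 of 22 did not pass, and adjusted over the list alone the count was also 2. The MHC class I list did not pass without PRE16cl11_VII (adjusted p = 0.0522) and the surface ectoderm list did not pass without Clone_287 (adjusted p = 0.0745).

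Other lists did not pass after a second transplantation but held members that did. In the thymic identity list Gata3 rose, Pax1, a pharyngeal pouch regulator, fell (2.47-fold) and 6 of 8 did not pass, with 1 higher and 3 lower when adjusted over the list alone. In the hair follicle stem cell list Vdr, the vitamin D receptor needed for the hair cycle, rose (3.16-fold) and 18 of 19 did not pass. In the epidermal differentiation list Calml3 rose (5.29-fold) and Cst6, a protease inhibitor, fell (2.27-fold), the latter with overlapping culture values. Scd (4.13-fold) and Acsl1 (2.65-fold), which act in lipid synthesis, rose, and Dgat2 of the same list fell (2.16-fold). Plaur (4.53-fold), its ligand Plau (2.46-fold) and Lcn2 (1.65-fold) fell in the inflammatory list. Isg15 (2.20-fold) and Ifi44 (1.59-fold) fell in the interferon list. Fst fell (5.58-fold), the apoptosis gene Bax fell (1.64-fold), Cd151, a hemidesmosome tetraspanin, fell (1.87-fold), and Hoxa5 (1.61-fold), Hoxa7 (2.34-fold) and the Wnt receptor Fzd6 (1.29-fold) rose.

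Between TEC cultures after a second transplantation and before grafting, limma called 591 probe sets, 295 higher and 296 lower. The count was 149 without PRP4mo_bulk, 150 without PRP4mo_Cl09, 251 without Clone_347, 279 without Clone_194, 303 without Clone_354 and 334 without PRP1cl11_VII. It was 35 with clonal cultures alone and 2070 with culture as a random block. Of the 47 genes named as changed, 21 stayed past the threshold whichever culture was left out, among them Lgals7, Ocm, Gpr15lg, Mme, Cdc42ep5, Plaur, Fst, Vdr, Hoxa7, S100a4 and Isg15. The calls of the other 26 ended in at least 1 case (adjusted p of 0.0505 to 0.133): 22 without PRP4mo_bulk, 21 without PRP4mo_Cl09, 18 without Clone_347, 16 without Clone_354, 14 without PRP1cl11_VII, 13 without Clone_287 or Clone_194 and 12 without PRE16cl11_VII. Krt8, Pax1, Klf4 or Psmb10, and Plau in 1 case, also ended without a culture of another group: 5 calls without Clone_907, 4 without Clone_217, 3 without Clone_218, YR219P5_RC or Clone_54, 2 without YR219P5_Bulk_V or YR219P5cl7 and 1 without Clone_57. With the arrays centred on their medians Krt8 (adjusted p = 0.0558), Psmb10 (0.0512), Pax1 (0.0525), Klf4 (0.0686) and Fzd6 (0.0518) did not pass, and with donor stage in the model Plau (0.0566), Pax1 (0.0672) and Klf4 (0.0535) did not.

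The changes after a first and after a second transplantation share the ungrafted control cultures. Of the genes called in both, 31 were higher in both and 43 lower in both, against 0 and 0 in 20 simulations with no effect and 0.636 and 0.889 for independent lists of these sizes, and 0 moved in opposite directions. With no effect almost no gene passes, so the simulated overlap says little, and the independent lists ignore the shared controls. With separate ungrafted cultures as controls, over 6 divisions, 0 to 4 were higher in both and 0 to 6 lower in both. The log2 changes correlated at 0.904 across genes (simulated 0.503; separate controls 0.613 to 0.782), with a covariance of 0.124 (simulated 0.0193; separate controls 0.0994 to 0.115). The sign was the same in 78.4% of genes (simulated 66.8%, separate controls 64.0% to 68.5%). The simulations kept the shared controls, so their values are a reference only for the comparison with shared controls. No values without an effect were computed for separate controls.

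Whether a further exposure adds to the first was asked by comparing TEC cultures after a second with those after a first transplantation, and no gene passed. Limma called 0 probe sets, with 532 at an unadjusted p under 0.05 where chance gives 766, and 0 were called with culture as a random block. With donor stage in the model 0 were called as well (693 at an unadjusted p under 0.05). The cultures were not paired across these states, since the labels give no descent. If some are related, this test can miss differences. The smallest p belonged to Acvr1, an activin receptor (log2 0.45 ± 0.10), and Polr2d (−0.55 ± 0.12), each with adjusted p = 1. Defb9 (0.32 ± 0.07), Uqcc3 (−0.44 ± 0.09) and Gng10 (−0.38 ± 0.09) followed. No gene list passed (0 of 28), the nearest being MHC class I presentation (median −0.16, adjusted p = 0.0687). Without Clone_287 the count was 136.

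What grafting does to cells that come from skin was asked by comparing HF cultures after and before a first transplantation, and no gene passed. Limma called 0 probe sets, 1354 had an unadjusted p under 0.05 where chance gives 766, and 49 were called with culture as a random block. The smallest p belonged to Lgals9, a galectin (log2 0.97 ± 0.20), Sp100 (at least 2.53, since its level in YR219P5_Bulk_V, 3.75, was not shown to lie above background) and Cds1 (1.92 ± 0.43), and to Jam3, a junction protein (−2.99 ± 0.56), Nfasc (−1.97 ± 0.35) and Pcyt1b (−0.99 ± 0.19), each with adjusted p = 0.562 and n = 2 cultures per group. The ungrafted cultures YR219P5_Bulk_V and YR219P5cl7 lay far apart in Jam3 (8.91 and 6.84), Nfasc (8.01 and 6.72), Sp100 (3.75 and 5.28) and Cds1 (5.86 and 7.88). The sizes of these differences therefore depend on single cultures, with YR219P5_Bulk_V the farther from the grafted cultures in each. Without YR219P5cl7 the count was 260. The number at an unadjusted p under 0.05 fell below chance without YR219P5_Bulk_V (268) and without YR219P5_RC (415), and was 2315 without Clone_54. The median log2 difference of all genes was 0.10, against 0.03 without array 1 of YR219P5_RC and 0.00489 with the arrays centred on their medians.

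After a first transplantation of HF cultures, 6 lists passed with camera, and 0 of their members passed over all genes. Fibroblast and feeder cell markers (median −0.10, adjusted p = 0.000319), basal keratinocyte and hemidesmosome genes (−0.29, 0.00228), the BMP and TGF-beta pathway (−0.17, 0.0194), p53 and senescence (−0.16, 0.0241) and inflammatory and wound response genes (median −0.02, mean −0.30, adjusted p = 0.0241) were lower, but each had adjusted p = 0.311 with an estimated correlation. Surface ectoderm transcription factors were higher (0.47, 0.0241), but had adjusted p = 0.556 with an estimated correlation. Adjusted over the list alone, Col5a2 was lower in the fibroblast list and the other 5 lists had 0. Without YR219P5_Bulk_V the lists for ectoderm (adjusted p = 0.56), BMP and TGF-beta (0.56), inflammation (0.0543) and fibroblasts (0.103) did not pass, and the medians of the BMP and TGF-beta (0.07) and fibroblast (0.06) lists lay above 0. Without YR219P5cl7 the p53 (0.26) and inflammatory (0.0663) lists did not pass, without YR219P5_RC the basal (0.242), BMP and TGF-beta (0.0832), p53 (0.548) and inflammatory (0.199) lists did not, and without Clone_54 the ectoderm list did not (0.738). With the arrays centred on their medians the p53 (0.0851) and inflammatory (0.11) lists did not pass.

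The change of TEC cultures on first transplantation differed from that of HF cultures in no gene past the threshold. Limma called 0 probe sets for the interaction of tissue and first transplantation, with 866 at an unadjusted p under 0.05 where chance gives 766, and 43 with culture as a random block. Lgals9 had the smallest adjusted p (log2 −1.72 ± 0.25, adjusted p = 0.126). Cdc42ep5 had an interaction of −3.44 ± 0.68 (adjusted p = 0.62) and Enpp1 of 2.84 ± 0.53 (adjusted p = 0.519). Rell2 (−1.16 ± 0.21) and Rin2 (1.21 ± 0.25) were among the next, and no gene list passed (0 of 28). The number at an unadjusted p under 0.05 was 441 without YR219P5_Bulk_V, 286 without YR219P5_RC and 1918 without Clone_54. The count was 75 without YR219P5cl7 and 1 without PRP4mo_bulk, and the median of all genes was −0.10.

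After a first transplantation of both tissues, TEC cultures stood above HF cultures in Isl1 (4.48-fold; 6.64 ± 0.20, n = 4, against 4.48 ± 0.24, n = 2; adjusted p = 0.0198) and Hoxa5 (3.30-fold; adjusted p = 0.00934). Ptgs1 was 13.1-fold higher, Steap2, a metalloreductase, 3.56-fold and Serpinb1a, a protease inhibitor, 2.37-fold. Ypel4 (2.41-fold), Lgals9 (2.25-fold), Cyp2d1 (1.77-fold) and Chrna2 (at least 1.45-fold, to 3.88, a level not shown to lie above background) were lower in TEC cultures. Pax9 differed by 1.89 ± 0.47 (adjusted p = 0.168) and Lhx2 by −0.72 ± 0.49 (adjusted p = 0.438). The thymic identity list was higher (median 0.36, camera adjusted p = 0.0172; adjusted p = 0.312 with an estimated correlation), with Isl1 past, 7 of 8 not past, and Pax9 and Isl1 past when adjusted over the list alone.

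The comparison of grafted TEC with grafted HF cultures asked which differences of origin remain after 1 transplantation. Limma called 11 probe sets, 7 higher and 4 lower, with the culture values of all named genes apart, and the median of all genes was −0.11 (−0.03 without array 1 of YR219P5_RC). Without YR219P5_RC limma called 0 (660 at an unadjusted p under 0.05), and without Clone_54 it also called 0 (3446). The count was 2 without Clone_217, 3 without Clone_218, 6 without PRE16cl11_VII, PRP1cl11_VII, PRP4mo_Cl09 or Clone_907, 7 without Clone_194, 0 with clonal cultures alone (581 at an unadjusted p under 0.05), 0 with only the cultures compared (2043), 7 after another quantile normalization, 33 with donor stage in the model and 249 with culture as a random block. All 9 named calls ended without YR219P5_RC (adjusted p of 0.0527 to 0.727) and without Clone_54 (0.0581 to 0.0913), 8 without Clone_217, 7 without Clone_218, 5 without PRP4mo_Cl09, 4 without PRE16cl11_VII, PRP1cl11_VII or Clone_907, 3 without PRP4mo_bulk, Clone_57, Clone_287 or Clone_194, 2 without Clone_354, YR219P5_Bulk_V or YR219P5cl7 and 1 without Clone_347. The thymic identity list did not pass without Clone_217 (0.0784), without YR219P5_RC (0.0744) or with the arrays centred on their medians (0.0799). With the arrays centred Chrna2 (0.102) and Ypel4 (0.0571) did not pass, with donor stage in the model Chrna2 did not (0.0517), and with culture as a random block Chrna2 (0.24) and Cyp2d1 (0.171) did not.

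After a second transplantation, TEC cultures still stood above grafted HF cultures in Hoxa5 (3.80-fold; 6.94 ± 0.25, n = 4, against 5.01 ± 0.35, n = 2; adjusted p = 0.00357) and Isl1 (3.69-fold; adjusted p = 0.0393). RT1-T24-1, a gene of the rat major histocompatibility complex (2.29-fold), Steap2 (3.35-fold) and Atp7a, a copper transporter (1.84-fold), were also higher. Ypel4 (2.38-fold) and Gng10, a G protein subunit (1.90-fold), were lower. Pax9 differed by 1.71 ± 0.47 (adjusted p = 0.12) and Lhx2 by −0.70 ± 0.49 (adjusted p = 0.418). The hair shaft and inner root sheath list was lower (median −0.25, camera adjusted p = 0.0467; adjusted p = 0.849 with an estimated correlation), with 0 of 21 members past and the hair keratins Krt28, Krt73, Krt81 and Krt85 lower when adjusted over the list alone.

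The comparison of TEC cultures after a second with HF cultures after a first transplantation asked which differences of origin remain after repeated exposure. Limma called 7 probe sets, 5 higher and 2 lower, and the median of all genes was −0.11 (0.03 with the arrays centred on their medians, when 91 were called). Without Clone_54 limma called 0 (3840 at an unadjusted p under 0.05). The count was 1 without YR219P5_RC, 3 without PRP4mo_Cl09 or Clone_354, 4 without Clone_194, 15 without Clone_347 and 450 without Clone_287. It was 0 with clonal cultures alone (527 at an unadjusted p under 0.05), 0 with only the cultures compared (2017), 4 after another quantile normalization, 25 with donor stage in the model, 43 over all probe sets, 721 with culture as a random block, 14 without array 1 of YR219P5_RC and 456 without array 2 of Clone_347, the last 2 settings being chosen after seeing the data. All 7 named calls ended without Clone_54 (adjusted p of 0.0514 to 0.0741), 6 without YR219P5_RC (0.0611 to 0.686), 4 without PRP4mo_Cl09, Clone_194 or Clone_354, 2 without Clone_217, YR219P5_Bulk_V or YR219P5cl7 and 1 without PRE16cl11_VII, PRP1cl11_VII, Clone_218, Clone_907 or Clone_347 (Isl1 or Steap2). The hair shaft list did not pass without Clone_287 (0.218), YR219P5_RC (0.19), Clone_354 (0.0952), Clone_194 (0.076), YR219P5_Bulk_V or YR219P5cl7 (0.0636 each), Clone_218 (0.0591) or Clone_57 (0.0524).

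No change in the distance of TEC cultures from HF cultures passed its test. Over all tested genes the mean distance of TEC cultures to ungrafted HF cultures changed by 0.00314 log2 units after a first and by 0.000219 after a second transplantation (two-sided exact permutation p = 0.971 for each). Without YR219P5_Bulk_V these changes were −0.0612 (exact p = 0.143) and −0.0701 (exact p = 0.2), and with clonal cultures alone −0.0584 and −0.0559. Both grafted states differed by −0.00292 (exact p = 0.971). The distance to grafted HF cultures (reference mean of n = 2) changed by −0.0936 and −0.0951 (exact p = 0.114 for each), and both grafted states differed by −0.00142 (exact p = 0.971). Culture distances to grafted HF ran from 0.4852 to 0.6006 before grafting, 0.3396 to 0.5287 after a first and 0.363 to 0.5621 after a second transplantation. Without Clone_347 the distance after a second transplantation changed by −0.134 (exact permutation p = 0.0286). These 6 tests were not adjusted for their number.

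**Figure D2:**
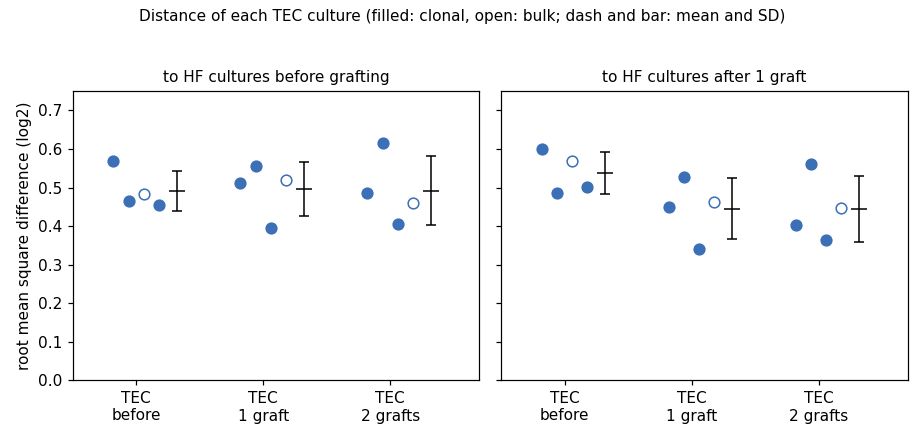
Root mean square log2 distance (vertical axis) of each of the 12 TEC cultures to the mean of the ungrafted and of the grafted HF cultures (panels), by number of transplantations (horizontal axis); points are cultures (filled for clonal, open for bulk), and bars give the group mean and SD. Distances to grafted HF cultures lay at 0.4852 to 0.6006 before grafting and at 0.3396 to 0.5287 after a first transplantation, so the ranges overlapped.

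Among the 29 to 69 genes that separated a part of the ungrafted TEC cultures from ungrafted HF cultures, grafted TEC cultures covered some of that difference. The mean share over 6 divisions was 34.0% (range 31.2% to 38.9%) after a first and 40.3% (37.4% to 43.7%) after a second transplantation. Ungrafted HF cultures measured the same way covered 87.6% (79.7% to 98.7%), and grafted HF cultures 72.1% (65.6% to 79.9%). No test was made of these shares.

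Whether donor age leaves a trace was asked by comparing TEC cultures of 4-month-old with those of E16 donors. RT1-CE5 (3.33-fold; adjusted p = 0.00349) and RT1-N2 (2.03-fold), both genes of the rat major histocompatibility complex, Slc22a18, a transporter (2.67-fold), Bbs10, a chaperonin-like protein of the cilium (2.57-fold) and Acadsb, which acts in the breakdown of branched-chain amino acids (2.13-fold), were higher at 4 months. Plscr2, a phospholipid scramblase (at least 11.4-fold, since its level in Clone_354, 3.89, was not shown to lie above background; log2 −3.52 ± 0.29 SE; adjusted p = 0.00349), Cyp2t1 (2.97-fold), Hpse, which encodes heparanase (1.99-fold), Terf2ip, a telomere protein (1.81-fold) and Rab7b (1.69-fold) were lower. Postnatal day 1 cultures, all clonal, lay at the 4-month level for RT1-N2 (6.66 to 6.93, against 5.39 to 5.86 at E16 and 6.59 to 6.68 at 4 months). The same held for Bbs10, Hpse and Terf2ip, so these differences set E16 apart and are not particular to 4 months. For Acadsb, Rab7b, Cyp2t1 and Plscr2 these cultures lay nearer E16, and for RT1-CE5 and Slc22a18 between. Limma called 14 probe sets, 8 higher and 6 lower, over 4 cultures of 4 months and 5 of E16. The count was 7 without Clone_347 or Clone_354, 9 without PRP4mo_bulk, 24 without Clone_287, 83 without Clone_907, 1 with clonal cultures alone, 24 over all probe sets, 27 with trend and robust settings and 488 with culture as a random block. RT1-CE5 and Plscr2 stayed past the threshold whichever culture was left out, but the 1 call with clonal cultures alone was none of the 14. The other 8 named calls ended in at least 1 case (adjusted p of 0.0502 to 0.187): 6 without PRE16cl11_VII, 5 without Clone_347, 4 without PRP4mo_bulk, PRP4mo_Cl09 or Clone_354, 2 without Clone_217, Clone_57, Clone_287 or Clone_194 and 1 without PRP1cl11_VII or Clone_218, and Bbs10 did not pass with the arrays centred on their medians (0.0666). Of the 4-month cultures 3 of 4 were bulk (PRP4mo_bulk, Clone_907 and Clone_354), and of the E16 cultures 0 of 5, so age and culture type were not separated. Cultures of one stage were treated as independent across transplantation states, which was not shown.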

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

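Of the tests in this part, only the count of splits for the gene totals and lists and the comparison of clonal cultures for the fibroblast list were written before their results were seen, and all others were chosen after. The requirements on spread, that all 3 collagens move together, and that they be lower for stromal cells to be excluded (first a median under 0.5), were added after the first values were seen and left the explanations concerned open.

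In 333 groups of 4 cultures, 29 values stood apart from the other 3 by more than Dixon's 95% limit for 4 samples, where chance gives about 1 in 20 groups, or 17. In ungrafted TEC cultures these were, in PRE16cl11_VII, Plaur at 10.85, Serpinb7 at 11.32, Prdm1 at 5.36, Pcyt1b at 3.86, Atp7a at 7.67 and RT1-N2 at 5.41. In PRP4mo_Cl09 Mme stood at 5.88 and Hoxa7 at 6.06, in PRP4mo_bulk Nupr1 at 5.37, and in PRP1cl11_VII Gpr15lg at 8.33. After a first transplantation, Clone_218 stood apart in Lgals7 at 6.94, Ctnnal1 at 7.62, Isg15 at 6.49, Sh3rf2 at 7.04, Plau at 10.17 and Chrm3 at 7.39. Clone_907 stood apart in Nts at 3.02, Cyp2t1 at 6.31 and Acadsb at 5.53, and Clone_57 in Sult1d1 at 5.51. After a second transplantation, Clone_354 stood apart in Isl1 at 7.04, Acadsb at 5.73 and Rab7b at 7.64, Clone_194 in Vamp5 at 8.49, Clone_347 in Ctnnal1 at 7.33 and B3gnt3 at 8.24, and Clone_287 in Ceacam1 at 6.99, Cst6 at 10.29 and Gng10 at 8.70. All are log2 signals, and no explanation was tested for them.

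The 13899 probe sets without exactly 1 gene symbol were left out of the comparisons, and limma called some of them. The numbers were 90 between TEC and HF cultures before grafting, 22 and 185 between TEC cultures after a first and a second transplantation and before grafting, and 5 and 26 between TEC cultures after a first and a second transplantation and grafted HF cultures. In the other 3 comparisons of this kind 0 were called.

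The ungrafted HF bulk culture YR219P5_Bulk_V lay apart from the other HF cultures: it correlated at 0.983, 0.975 and 0.975 across genes with YR219P5cl7, YR219P5_RC and Clone_54, which correlated with each other at 0.992 to 0.996. The tables argue against a single poor array, since its arrays differed by 0.174 where it differed from YR219P5cl7 by 0.464 (share 0.374). Stromal cells stay open: Col1a1, Col1a2 and Col3a1 were 0.270 to 0.327 higher than in the clone (median 0.283). S100a4 (9.37 against 8.27) and Loxl1 (8.10 against 5.71) were higher too, while Twist1 was close (6.17 against 6.05). Ungrafted clonal TEC cultures reached 9.45 in S100a4 (PRP4mo_Cl09) and 9.88 in Loxl1 (PRE16cl11_VII), so such levels also occur in clones. Bulk culture as such stays open, since the better correlation of the grafted bulk culture with the clone, by 0.0174, restates the pattern and decides nothing. A biological difference, a wrong label, passage number or culture conditions may contribute and were not tested.

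Fibroblast and feeder cell markers were lower in TEC cultures after a second transplantation (median log2 −0.30), although the list had adjusted p = 0.632 with an estimated correlation. Carry-over of feeder cells or fibroblasts before grafting may contribute and stays open: the collagens changed by a median of −0.377, but Col1a1 by −0.01 ± 0.13 SE, Col1a2 by −0.38 ± 0.15 and Col3a1 by −0.42 ± 0.26, and Col1a1 stood at percentile 55.5 of all genes before grafting. Mixed cells in the bulk cultures also stay open: in the 6 clonal cultures the list changed by −0.172, and by −0.245 to −0.121 when each was left out. The feeder cells are from mice, and how well their RNA binds these probes was not tested. A change of the epithelial cells themselves stays open and untested.

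The E16 cultures after a first and a second transplantation resembled each other in pairs: Clone_217 with Clone_287 (correlation 0.995) and Clone_218 with Clone_347 (0.990), against 0.987 for Clone_217 with Clone_347 and 0.983 for Clone_218 with Clone_287. The difference between both E16 cultures after a first transplantation correlated with that after a second at 0.436 across genes, where unrelated pairs reached at most 0.211 in size. Single arrays gave 0.0608 to 0.529, so donor stage alone stays open. A shared array run stays open as well: the correlation across array numbers was 0.612 of that within them (0.280 and 0.457). A shared line of descent, which the labels do not give, is a further hypothesis that was not tested.

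For the counts of genes, other divisions of the same cultures were tried. Between TEC cultures after a second transplantation and before grafting the real division called 591, the highest other called 0, and 1 of 35 divisions reached the real count. That share is the smallest the test can give, and it was not adjusted for the number of such tests. It argues against chance only if the cultures are independent, which the labels do not show. After a first transplantation chance cannot be excluded: 2 of 35 divisions called at least the real 79, and the highest other called 711, which points to a structure of the samples. That division set Clone_217, Clone_218, Clone_907 and PRE16cl11_VII against Clone_57, PRP1cl11_VII, PRP4mo_bulk and PRP4mo_Cl09. For gene lists chance cannot be excluded either: 10 of 35 divisions reached the real 3 after a first transplantation (highest other 7) and 15 of 35 after a second (real 3, highest other 9). Between both grafted states all 35 divisions reached the real 0, and the highest other called 68. For donor age 1 of 27 divisions reached the real 14, with 2 as the highest other. This argues against chance only if cultures of one stage are independent across transplantation states, which the pairs above leave open, and culture type stays confounded with age.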

How the results depend on the processing

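Fits without array 1 of YR219P5_RC and without array 2 of Clone_347 were chosen after seeing the data, and all other settings before. Direction was examined only for named genes, with a random block, donor stage in the model, median centring and each culture left out. There no gene past the threshold changed direction. Foxn1, never past it, ranged from −0.18 to 0.71 between TEC and HF before grafting and from −0.07 to 0.05 and −0.14 to 0.03 after a first and a second transplantation when cultures were left out, and Cd74 from −0.41 to 1.22 before grafting. Without YR219P5_Bulk_V the medians of the BMP and TGF-beta and fibroblast lists in HF after with before turned to 0.07 and 0.06. Of 6 distance differences 4 changed sign under some setting, none past its test in either direction. Where a setting leaves 1 HF culture in a group, that culture is assumed to vary like the other groups. The filter on dim probe sets kept all 9 gene counts within 1.5 times, and signal over background limits the precision of dim probe sets. Of the other gene counts 7 of 9 stayed within 1.5 times over all probe sets and after quantile normalization, and 8 of 9 with median centring and with trend and robust settings. Of 144 results for named genes, 133 kept their side of the threshold with median centring and 136 with a random block, and 48 whichever culture was left out. Of 16 gene list results past the threshold, some of them for the same list in several comparisons, 13 stayed past it with median centring. Whichever culture was left out 2 stayed past it, and with an estimated correlation 0. Those 2 were the fibroblast and feeder cell markers in TEC cultures after a first and a second transplantation, which share the ungrafted controls.

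Comparisons are given in the order TEC with HF before grafting, TEC after a first and a second transplantation with before, grafted TEC states with each other, HF after with before, TEC after a first and a second transplantation with grafted HF, interaction, and donor age. With culture as a random block the counts were 977, 1183, 2070, 0 (774 at an unadjusted p under 0.05), 49, 249, 721, 43 and 488, and with the array number as a replicate block 944, 1132, 2014, 0 (764), 36, 219, 670, 34 and 448. The array numbers do not mark the same pairing in all cultures. Differences between the arrays correlated above 0.1 in 23 of 120 pairs of cultures (median −0.0107, range −0.635 to 0.574). Negative correlations were not counted, and the sign depends on how the arrays were numbered. A technical factor shared by the arrays of some cultures therefore stays open and was not tested. Arrays of a culture had a consensus correlation of 0.559, which these fits applied to every gene. For genes that vary more between cultures than this implies, the arrays count as extra replicates and the p-values are too small. How much of the larger counts this accounts for was not tested. With clonal cultures only the counts were 4, 0 (1308 at an unadjusted p under 0.05) and 35 in the first 3 comparisons, 0 (581) and 0 (527) against grafted HF and 1 for age, and the covered share after a first transplantation was 38.6%; fewer cultures were tested. With donor stage of the TEC cultures in the model the first 2 counts were 423 and 143, and those against grafted HF 33 and 25. With only the cultures compared, TEC after a first transplantation against before gave 17, and the comparisons with grafted HF 0 (2043) and 0 (2017). Against grafted HF, quantile normalization gave 7 and 4, and for the second transplantation median centring gave 91, all probe sets 43, the fit without array 1 of YR219P5_RC 14 and that without array 2 of Clone_347 456. For age, all probe sets gave 24 and trend and robust settings 27. With an estimated correlation 0 lists passed in each of the 8 comparisons. Except where stated, the cause was not tested.

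Leaving out each culture in turn gave 18 to 375, 8 to 148, 149 to 674, 0 to 136, 0 to 260, 0 to 12, 0 to 450, 0 to 75 and 7 to 83 genes, the lowest and highest of the first 3 coming without YR219P5_Bulk_V and YR219P5cl7, Clone_217 and Clone_57, and PRP4mo_bulk and Clone_287. The lists past the threshold ranged from 0 to 6, 1 to 5, 2 to 5 and 3 to 7 in the first 3 comparisons and HF after with before. The distance to grafted HF after a second transplantation changed by −0.0951 with all cultures and by −0.136 (without YR219P5_RC) to −0.0491 (without Clone_54) with 1 left out. It passed only without Clone_347 (−0.134, exact permutation p = 0.0286).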

Other observations

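All values in this part come from comparisons fixed before the data were examined, except that the other probe sets were examined after the results of the named genes were seen.

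Of the 28 gene lists, 18 passed with camera in none of 8 comparisons, and the smallest adjusted p of each follows. For HF cultures after against before grafting it was 0.301 for thymic epithelial function, 0.274 for MHC class II presentation, 0.0776 for epidermal differentiation (median log2 0.55), 0.453 for the Wnt pathway (test lower, median 0.06, mean −0.02), 0.136 for cell cycle (median 0.38), 0.125 for melanocyte, 0.579 for endothelial and 0.501 for muscle markers. Between TEC and HF cultures before grafting it was 0.151 for the interferon response, 0.0696 for simple and endodermal epithelium (median 0.14, mean 0.78) and 0.052 for the Hedgehog pathway (median −0.21). Between TEC cultures after a first transplantation and before grafting it was 0.397 for sebaceous and lipid synthesis and 0.375 for Hox paralogues of high number, and after a second 0.301 for the Notch pathway. Between TEC and HF cultures after a first transplantation it was 0.34 for Hox paralogues of low number (test higher, median −0.10, mean 0.21), 0.252 for haematopoietic and 0.226 for parathyroid and thyroid markers. For nerve markers it was 0.649, between TEC cultures after a second transplantation and grafted HF cultures. No member of the MHC class II, Notch, Hedgehog, cell cycle, melanocyte, haematopoietic, endothelial, nerve, parathyroid or muscle lists passed over all genes in any of the 8 comparisons.

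Some genes had a further probe set. After a second transplantation of TEC cultures, those of Bax (log2 −0.71, adjusted p = 0.0197), Psme2 (−0.76, 0.0156) and Klf4 (0.98, 0.0143) passed in the same direction as the named ones. The other probe set of Lgals9 differed by −0.01 between TEC and HF cultures before grafting, by −0.19 in TEC cultures after a first and by −0.01 after a second transplantation, and did not pass (adjusted p = 0.991, 0.497 and 0.988). The named Lgals9 probe set differed by 0.547, −0.753 and −0.565 there, so the probe sets did not match. In the comparisons for which Lgals9 is named above, its other probe set was not examined.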
